A study of Oncorhynchus mykiss with 70 samples.

How the data were processed

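RNA from 70 samples of 23 adult rainbow trout tissues was measured with a custom NanoString code set of 66 probes: 49 pathway genes, the reference genes actb, ef1a and tbp, 6 positive controls and 8 negative controls. Per the labels, the fish came from the Swanson and Oregon State University clonal lines, were kept in recirculating systems without treatment, and RNA was extracted with reagents that varied by tissue. Samples of embryos, fry, parr and juveniles that the design text names were not analysed here.

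The authors deposited raw barcode counts, whole numbers with 1 value per probe and sample, not normalized and not background-corrected. No count was 0 and the lowest count in every sample was 1, so values of 0 may have been raised to 1 before deposit. A second deposited table holds the authors' normalized signal, 1 value per gene and tissue, in which replicates are pooled; its method is not given in the sources used here. The signal table was used only to find which samples share a scale in it and to set ranks side by side. The authors' gene list (59 genes in the larger list) and probe list (100-base targets) gave gene identity, chromosome and notes on shared probes; all 49 panel genes matched RefSeq gene identifiers of the assembly USDA_OmykA, and for 2 genes the chromosome differs between the lists. Another sheet with an earlier naming was not used. No column of per-sample values was left out.

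The design written before the data were examined assumed normalized values and limma. The deposited files hold counts, so edgeR 4.0.16 (quasi-likelihood) in R 4.3.3 was used on the counts, with each sample's offset from the geometric mean of its 3 reference genes, and limma 3.58.1 on log2(scaled count + 10) became an alternative. One model with a coefficient per tissue was fitted to all 70 samples. An F-test asked for variation among the 23 tissues and among the 7 skeletal muscles. Contrasts compared Red Skeletal Muscle and Extraocular Muscle with the mean of 5 other skeletal muscles, Ovaries with Testes, Heart with Bulbus Arteriosus, Brain with Retina, and each tissue with the mean of the other 22. For skeletal muscle against other tissues the counts of a tissue's samples were summed, so that the tissue was the unit. Heart, Bulbus Arteriosus and Tongue are not titled muscle and counted among the others. All tests were two-sided, with Benjamini-Hochberg adjustment over the 49 genes (1127 gene and tissue pairs, 21 duplicate pairs) and a threshold of 0.05. A pair was enriched with a log2 difference of at least 1 and a mean count of at least 20 in the tissue, and depleted with a difference of −1 or lower.

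Duplicate pairs were the genes that share a name up to the final number. A change of use between tissues was tested with edgeR's quasi-likelihood test of copy by tissue, each sample keeping its own level; a constant ratio is not tested, since probes may differ in efficiency. A quasi-binomial test tried first was replaced because it gave false calls on simulated data. Correlations over tissue means of log2(scaled count + 10), and within tissues over samples, were tested with 100000 permutations in R or Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Figures were drawn with matplotlib 3.10.9.

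The named genes follow a rule set in advance. In each comparison of 2 sides up to 12 genes per direction with the largest difference were named, among those past the threshold with a mean count of at least 20 in the higher side. For variation among tissues or muscles, the 5 widest and 5 narrowest ranges of tissue means were named, among genes whose highest tissue mean reaches 20, with 50 as an alternative minimum. Up to 2 enriched genes per tissue were named, and the 5 pairs of lowest and 3 of highest r. In the muscle comparison the myostatins were always named, and gdf11, inhibin and activin chains, follistatin and acvr2 genes summarised. Gene lists were fixed by symbol in advance: ligands, extracellular antagonists, co-receptors and decoys, type I receptors, type II receptors, receptor-regulated and common Smads, inhibitory Smads, with the rest (inhbcb1, inhbcb2) as other pathway genes. The lists of ligand processing genes and of muscle markers had no member in the panel, so no check of cell type could be made.

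Sets of samples that share a scale in the authors' table were sought by matching the authors' signal per tissue to the counts. Set A holds 44 samples of 15 tissues, set B 12 of 4 (Retina, Cardiac Stomach, Distal Intestine, Pelvic Fin) and set C 13 of 6 (Caudal Skeletal Muscle, Red Skeletal Muscle, Heart, Gill and some samples of Pelvic Fin Skeletal Muscle and Adductor Skeletal Muscle). Adductor Skeletal Muscle 1 is in none. Total counts ran from 52194 to 269554 per sample. No replicates were copies of each other, with a lowest chi-squared per degree of freedom of 2.40 between any pair of replicates. Precision at low counts is limited by background, whose mean was 2.5 to 11.5 counts per negative control.

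The procedure was tested on simulated data, 20 rounds with 8 changed genes per size of change, and fewer for the duplicate pairs. Counts were drawn at the samples' own depths and at each gene's mean over all 70 samples, not at its mean in each tissue. Genes near background in single tissues and samples unlike their replicates were therefore not reproduced. The shares and false calls need not hold for them. For Ovaries against Testes the procedure recovered 13.1% of genes changed by log2 1 and 64.4% of those changed by log2 2. There were 2 false calls among 660 unchanged. The shares were 25% and 66.2% for red muscle, 25% and 75% for extraocular muscle, and 38.8% and 93.8% for the muscle class (3, 3 and 10 false calls of 660). For an SD between tissues of 0.5 and 1 they were 48.8% and 92.5% over 23 tissues, 24.4% and 57.5% over 7 muscles (3 and 4 false calls of 660), and 15% and 77% for the duplicate pairs (2 of 220). Enriched pairs of log2 1.5 and 2.5 were recovered in 48.8% and 91.2% of cases (10 of 22220).

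Alternatives set in advance were other pseudocounts, pathway scaling, a filter at 50, robust variance moderation, a block for replicate number, samples as units, only the tissues compared, other choices of which tissues count as muscle or as other, the 7 muscles averaged to 1 tissue, a median reference, a Kruskal-Wallis test, a log2 minimum of 2, and leaving out each sample in turn. Alternatives chosen after seeing the data were limma, subtraction of the negative controls, TMM, ef1a with tbp, tbp, the positive controls, DESeq2 1.42.0 with its own size factors, omission of the 8 samples with few detected genes, of samples with joint inhibin and myostatin counts and of 4 samples unlike their replicates, and the sets as a block or one at a time. Random regroupings of the samples, or of the tissues for the muscle class, were run as well, at most 100 per comparison.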

Results

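RNA of 49 genes of the activin receptor pathway was counted in 23 tissues of untreated adult rainbow trout from clonal lines, to map where each gene and each of its duplicates is expressed. The NanoString assay used here counts colour-barcoded probes bound to RNA, without amplification. The panel held 15 ligand probes, 10 type I receptors, 7 type II receptors, 10 receptor-regulated and common Smads, 2 inhibitory Smads, 2 probes of the decoy receptor bambi, 1 of the antagonist follistatin and 2 of the activin beta C chain. Of the 70 samples, 22 came from 7 skeletal muscles and 48 from 16 other tissues. Caudal Skeletal Muscle had 2 replicates, Pelvic Fin Skeletal Muscle and Adductor Skeletal Muscle had 4 each, and the other 20 tissues had 3 each. The design text calls the replicates biological. In most tests here p-values measure only the spread between these samples. For skeletal muscle against other tissues they measure the spread between tissue totals. That comparison takes the 7 muscles as independent units, which was not tested. All fish were male except the source of the ovaries, and the method of RNA extraction varied by tissue. Total counts per sample ran from 52194 in Red Skeletal Muscle 2 to 269554 in Pyloric Caeca 2, and the 49 pathway genes took between 511 (Adductor Skeletal Muscle 1) and 46159 (Ovaries 2). Between 7 and 48 of the 49 genes per sample exceeded the mean plus 2 SD of the negative controls, and in 8 samples the number was 24 or lower. Each negative control averaged between 2.5 and 11.5 counts per sample, so values near that level are not distinguishable from background.

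Levels are given as reference-scaled counts, which divide each sample's counts by the geometric mean of actb, ef1a and tbp relative to the average sample. This factor was low in muscle, with a median of 0.349 in the 22 muscle samples and 1.72 in the other 48. Splits into higher and lower are therefore also given with pathway scaling, which uses the mean of the pathway genes in place of the reference genes. Several probes bind more than 1 gene copy according to the authors' list: the mstna1 probe binds both copies of that myostatin, the fsta probe 2 follistatin loci, the inhab1 probe also the locus of inhab2, the smad2a2 probe both smad2a and smad2b, and the acvr2ba1 probe also the locus of acvr2ba2. The authors' own table of tissue values, set against the counts, parts the samples into 3 sets with a scale each, called A (44 samples), B (12) and C (13) below. Chromosome numbers below are those of the authors' gene list.

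All 49 genes differed among the 23 tissues by edgeR's quasi-likelihood F-test, and 48 by a Kruskal-Wallis permutation test, which did not call inhbbb1 (permutation p = 0.187, adjusted p = 0.187; named here after its values were seen). The widest range belonged to mstna1 (chromosome 22), a myostatin, which is a secreted inhibitor of muscle growth. Its level fell from 1663 ± 519 (SD, n = 2) in Caudal Skeletal Muscle to 3.93 ± 4.27 (SD, n = 3) in Gill, a range of 6.91 on the log2 scale. The probes for the inhibin alpha chain, which pairs with activin beta chains to form inhibins, came next and peaked in the gonads. The inhab1 probe (chromosome 18) reached 2170 ± 1836 (SD, n = 3) in Ovaries, and inhab2 (chromosome 7) reached 1694 ± 1413 there and 888 ± 53.7 in Testes (SD, n = 3 each). On the mean of log2 values Testes was highest for inhab2; Ovaries 3 held 170 inhab2 counts and its replicates 12850 and 12391. The type I receptor acvr1ca1 (chromosome 22), an ALK7 gene, ranged from 798 ± 451 (SD, n = 3) in Visceral Fat to 3.44 ± 0.837 in Pyloric Caeca (F = 19.9, and 32.3 without Tongue 3). The activin beta C gene inhbcb2 (chromosome 7) spanned 5.28 on the log2 scale and was highest in Caudal Skeletal Muscle at 557 ± 74.8 (SD, n = 2). At the other end, the narrowest ranges were 1.76 for inhbaa2, 1.90 for smad3a2, 1.90 for acvr2bb, 1.93 for smad2a2 and 2.19 for acvr1aa1. The smad2a2 probe, which reads a signal transducer shared by activin receptors, still ranged from 561 ± 24.0 in Testes to 141 ± 21.7 in Pyloric Caeca (SD, n = 3 each). Every list had all its members past the threshold, the same when adjusted over the list alone; with pathway scaling 8 of the 10 receptor-regulated and common Smads passed. edgeR's quasi-likelihood F-test gave adjusted p = 5.33e-05 for smad3a2, the largest among these genes of widest and narrowest range, and that call was lost once the negative controls were subtracted. With the sets as a block all 49 passed.

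**Figure D1:**
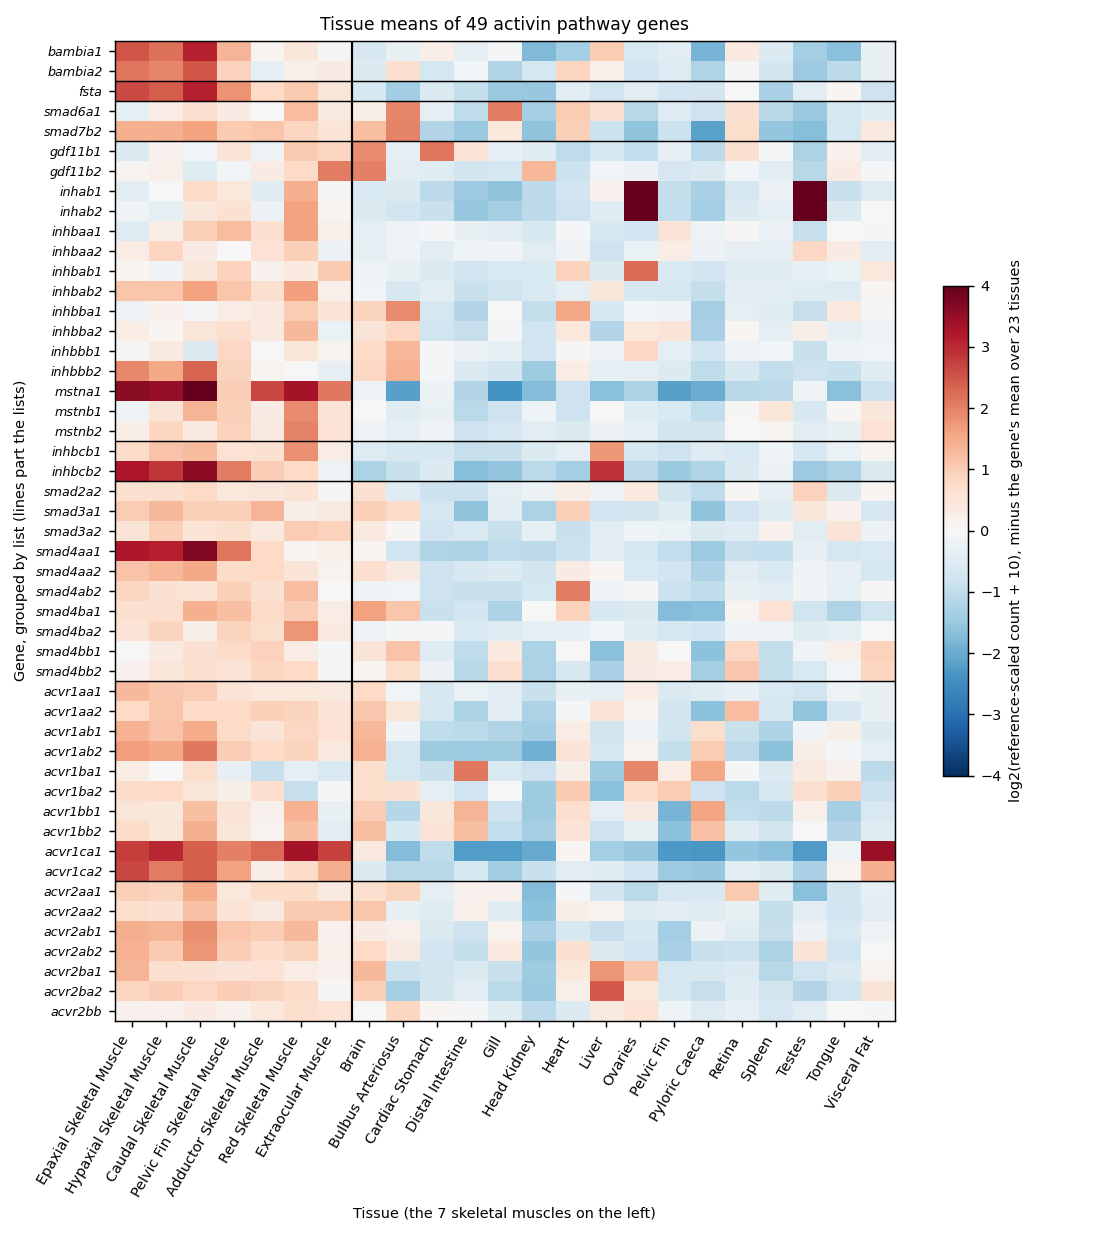
Heat map of the 49 genes (vertical, grouped by list) in the 23 tissues (horizontal, the 7 skeletal muscles on the left); colour is the tissue mean of log2(reference-scaled count + 10) minus the gene's mean over the 23 tissues, limited to 4 in either direction. Red marks tissues above a gene's mean, as for inhab1 and inhab2 in both gonads, inhbcb2 in Liver and acvr1ca1 in Visceral Fat.

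Each tissue was then set against the mean of the other 22, which shows where a gene is concentrated. The inhibin alpha probes were concentrated in Ovaries (log2 6.33 ± 0.48 (SE) for inhab1 and 6.46 for inhab2) and in Testes (5.38 and 5.49). Visceral Fat was marked by acvr1ca1 (4.28 ± 0.36 (SE), 19.4-fold) and by its duplicate acvr1ca2 (2.35; 1.57 and no longer past the threshold without Visceral Fat 3). Liver was marked by the activin beta C genes inhbcb2 (4.05; 514 ± 467, SD, n = 3) and inhbcb1 (3.60; 1.75 without Liver 1), whose relatives in mammals are made mainly by the liver. In Brain the myostatin relatives gdf11b2 (2.87; chromosome 7) and gdf11b1 (2.37; chromosome 17) stood out, and gdf11b1 was also concentrated in Cardiac Stomach (2.59; 153 ± 6.52, SD, n = 3). Head Kidney was high in gdf11b2 alone of that pair (1.85). Among the type I receptors, acvr1ba1 was enriched in 3 tissues, of which Distal Intestine (2.45) and Pyloric Caeca (1.78) belong to the gut, and acvr1bb1 in 5 tissues, among them Pyloric Caeca (1.80; 318 ± 121, SD, n = 3) and Distal Intestine (1.49; 259 ± 1.42, SD, n = 3). The inhibitory Smad smad6a1 was concentrated in Bulbus Arteriosus (2.51; 1.57 without Bulbus Arteriosus 1) and Gill (2.35), and the activin beta B gene inhbba1 in Bulbus Arteriosus (2.61; 164 ± 125, SD, n = 3). Heart was marked by the common Smad smad4ab2 (2.75) and by inhbab1 (2.21; 1.61 and no longer past the threshold without Heart 2). Retina was marked by acvr1aa2 (1.43) and smad4bb2 (1.25), and Pelvic Fin by acvr1ba2 (1.26; 0.91, below the minimum of 1, without Pelvic Fin 2).

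Among the 7 muscles, mstna1 was one of the leading genes in Caudal Skeletal Muscle (4.95), Extraocular Muscle (4.25), Hypaxial Skeletal Muscle (4.02), Epaxial Skeletal Muscle (4.00), Red Skeletal Muscle (3.69) and Adductor Skeletal Muscle (3.55). In Pelvic Fin Skeletal Muscle inhbcb2 (2.98) and smad4aa1 (2.85) led. Tongue was called for acvr1ca1 (1.91) and acvr1ca2 (1.97) through Tongue 3 alone: acvr1ca1 read 477 there and 10.4 and 10.5 in the other Tongue samples, and the differences were −2.07 and −1.84 without it. In total 184 of 1127 gene and tissue pairs were enriched (edgeR's quasi-likelihood test, adjusted p below 0.05, log2 difference of at least 1, mean count of at least 20) and 188 were depleted. Of the 184, 119 lay in the 7 muscles and 65 in the 16 other tissues. With the 7 muscles averaged to 1 tissue 132 pairs were enriched, 29 in muscle and 103 in the 16 other tissues. With pathway scaling 149 pairs were enriched, 42 of them in muscle, and 101 were depleted; 94 pairs were enriched under both scalings. With the 7 muscles counted separately only inhbab2 and smad2a2 were enriched in no tissue, and 7 genes in 1 tissue; with the muscles averaged inhbab2 was enriched in Liver (1.92) and smad2a2 in Testes (1.16). These comparisons share samples, so the counts per tissue are not independent. With the sets as a block 172 pairs were enriched, 167 of them among the 184.

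Skeletal muscle as a class was compared with the other tissues by taking each tissue as a unit, 7 against 16. The mstna1 level averaged 863 ± 447 (SD, n = 7) in muscle and 31.4 ± 34.9 (SD, n = 16) elsewhere, a 26.1-fold difference (log2 4.71 ± 0.53 (SE), adjusted p = 6.4e-08). The common Smad smad4aa1 (chromosome 6), a shared partner of receptor-activated Smads, was 12.7-fold higher (333 ± 273 against 23.7 ± 9.68; log2 3.67). Follistatin, which binds and blocks activins and myostatin, was 9.63-fold higher (fsta, chromosome 6; 156 ± 99.7 against 14.6 ± 8.98; log2 3.27). The second myostatin pair was higher too, at far lower counts: mstnb1 (chromosome 7) averaged 61.3 ± 56.7 against 10.3 ± 7.06 (log2 2.12 ± 0.46 (SE), adjusted p = 0.000344), and mstnb2 (chromosome 18) 46.6 ± 47.4 against 5.95 ± 4.60 (log2 2.56 ± 0.45 (SE), adjusted p = 3.62e-05). For each of the genes named here, all 7 muscles lay above the median of the other tissues. For mstnb1 and mstnb2 this rests in some muscles on background-level counts divided by a low reference factor. In Epaxial Skeletal Muscle they averaged 2.67 and 3.33 counts, and in Caudal Skeletal Muscle mstnb2 averaged 2.5. These means were 0 once the negative controls were subtracted. The other muscles kept 1.31 to 66.0 counts of mstnb1 and 2.5 to 54.6 of mstnb2.

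By list, 7 of the 15 ligands (6 adjusted over the list alone), 6 of the 10 type I receptors, 4 of the 7 type II receptors, 6 of the 10 receptor-regulated and common Smads, fsta, both bambi probes and both inhbcb probes were higher in muscle, and neither inhibitory Smad passed. Apart from the ligands, these counts were the same when adjusted over the list alone. Among the receptors, acvr1ca2 was 2.47 and acvr1ca1 2.27 higher on the log2 scale; without Extraocular Muscle 1 acvr1ca1 no longer passed (2.07, adjusted p = 0.055). All 4 acvr2a genes passed, with acvr2ab1 at 1.88 and acvr2ab2 at 1.53, while the acvr2b genes did not. The decoy receptor genes bambia1 and bambia2 were 2.22 and 2.03 higher, and inhbcb2 2.44. Of the inhibin and activin chains, inhbaa1, inhbaa2, inhbab2 and inhbbb2 (1.54) passed, and neither gdf11 gene did. The inhbaa2 counts were near background, at 11.7 in Extraocular Muscle, 5.33 in Red Skeletal Muscle and 7.23 over the other 5 muscles. With the negative controls subtracted 4 ligands were higher.

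The class test was edgeR's quasi-likelihood test on tissue sums, which called 28 of 49 genes, all higher in muscle, with a median difference of +1.13 over the panel. With pathway scaling the median shifted to −0.31 and 5 genes were higher and 7 lower. Higher under both scalings were mstna1 (3.32 with pathway scaling), smad4aa1 (1.96), fsta (1.58), mstnb2 (1.14, adjusted p = 0.0491) and inhbab2 (0.97), while smad2a2 turned from 0.65 to −0.92. The inhbab2 counts were low, at 27.7 in Extraocular Muscle, 9.67 in Red Skeletal Muscle and 12.3 over the other 5 muscles. By list, pathway scaling left 3 ligands higher and 1 lower, 2 type I receptors lower, 1 type II receptor lower, 1 Smad of the receptor-regulated and common list higher and 2 lower, 1 inhibitory Smad lower, fsta higher, and no bambi or inhbcb probe past the threshold. TMM gave 4 higher and 2 lower, DESeq2 with its own size factors 6 and 10, and the positive controls 2 and 21. Leaving out the samples with joint inhibin and myostatin counts described below gave 23 genes, with mstnb1 at 1.37 and mstnb2 at 1.30, each over 1.5 times smaller as a log2 value. Within set A 18 genes were higher and 0 lower in muscle, and within set C 8 and 0 (21 and 16 genes at an unadjusted p below 0.05); set B holds no muscle, and the sets as a block left 27 calls.

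**Figure D2:**
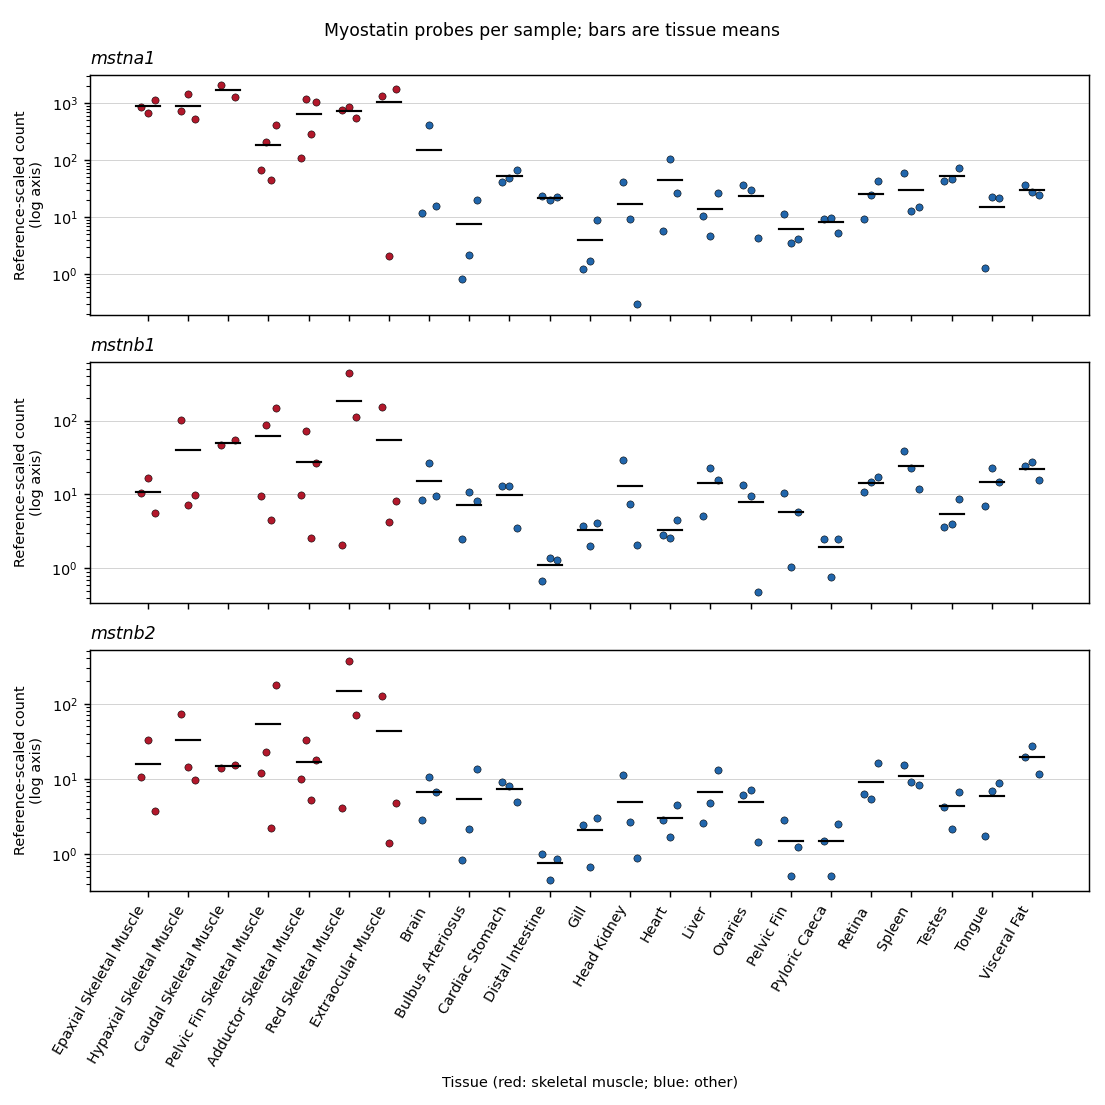
Reference-scaled counts (vertical, log axis) of the 3 myostatin probes in each sample of the 23 tissues (horizontal; red points, skeletal muscle; blue points, other tissues; bars, tissue means). For mstna1, 1 Extraocular Muscle sample lies at 2.10 and 1 Brain sample at 417, apart from their replicates.

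**Figure D3:**
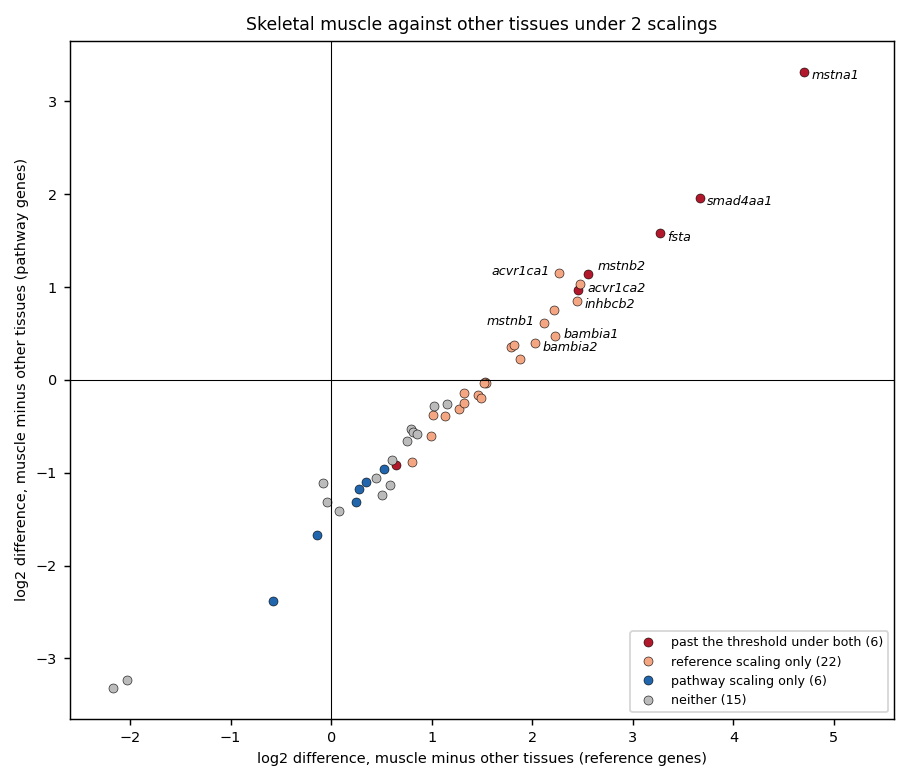
Log2 difference of skeletal muscle from other tissues for each of the 49 genes with reference-gene scaling (horizontal) and pathway scaling (vertical). The panel's median is 1.13 on the horizontal axis and −0.31 on the vertical axis; red points passed under both, 1 of them, smad2a2, with opposite signs.

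Among the 7 muscles themselves, 10 genes differed. The most variable by test was smad4aa1, at 731 ± 12.7 (SD, n = 2) in Caudal Skeletal Muscle and 69.7 ± 73.2 (SD, n = 3) in Red Skeletal Muscle (adjusted p = 1.83e-08, edgeR's quasi-likelihood F-test). Caudal Skeletal Muscle was also highest in both decoy receptor genes. There bambia1 read 1115 ± 26.5 (SD, n = 2), against 130 ± 78.9 (SD, n = 3) in Extraocular Muscle, and bambia2 read 229 against 23.1 in Adductor Skeletal Muscle (F = 4.62, and 7.22 without Red Skeletal Muscle 2). For inhbcb2 the span was 557 ± 74.8 to 58.5 (adjusted p = 0.0362), a call lost without any 1 of 10 single samples, with F falling from 3.33 to 2.71 without Extraocular Muscle 3. The mstna1 means spanned 3.53 on the log2 scale, from 1663 in Caudal Skeletal Muscle to 185 ± 171 (SD, n = 4) in Pelvic Fin Skeletal Muscle, and the gene did not pass (adjusted p = 0.348; 0.212 without Extraocular Muscle 2), with an SD between replicates of 1.76 on that scale; with limma at a pseudocount of 50 it passed. The smallest spans were acvr2bb 0.52, acvr1aa2 0.56, smad3a2 0.62, acvr2aa2 0.82 and smad4bb2 0.83, none past the threshold. However, by edgeR's quasi-likelihood F-test acvr2aa2 passed without Extraocular Muscle 2 (adjusted p = 0.0231) and with pathway scaling (adjusted p = 0.0115). By list, 3 of 15 ligands, 2 of 10 receptor-regulated and common Smads, 1 of 10 type I receptors, fsta, both bambi probes and inhbcb2 passed, the same adjusted over the list alone, and no type II receptor or inhibitory Smad did. Within set A 3 genes passed and within set C 2 (14 and 8 at an unadjusted p below 0.05). The number was 18 without Red Skeletal Muscle 1 or without Extraocular Muscle 1.

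Red muscle was set against 5 other skeletal muscles to ask about fibre type. The common Smad smad4aa1 was lower in red muscle, 69.7 ± 73.2 (SD, n = 3) against 439 ± 250 (SD, n = 5 tissue means), by log2 −2.52 ± 0.52 (SE, adjusted p = 0.000507). The type I receptor acvr1ba2 was lower as well (29.7 ± 21.9 against 95.7 ± 17; −1.75, adjusted p = 0.0233), and that call was lost without Red Skeletal Muscle 1 (−1.40) or Red Skeletal Muscle 3 (−1.52). The 7 genes called higher all averaged fewer than 20 counts on both sides and so fall outside the rule for naming: 5 of the 15 ligands (8 adjusted over the list alone), including mstnb2 and mstnb1, named here after their values were seen, and 2 common Smads. In Red Skeletal Muscle 2 the counts of inhab1, inhab2, mstnb1 and mstnb2 were 41, 35, 40 and 34; with such samples left out, 0 genes were higher and 6 lower. By list the Smads had 3 of 10 called (2 higher, 1 lower), the type I receptors 1 of 10 and the others 0, the same adjusted over the list alone. edgeR's quasi-likelihood test called 9 genes (7 higher, 2 lower; 17 at an unadjusted p below 0.05). Pathway scaling gave 8 higher and 7 lower, TMM 6 and 6, ef1a with tbp 0 and 2, tbp 0 and 6, and the positive controls 0 and 1. With the sets as a block, and within set C (3 samples against 4), edgeR called 0 genes, with 11 at an unadjusted p below 0.05 each. The block left smad4aa1 at −2.13 (edgeR, adjusted p = 0.0548). The block's difference between sets C and A rests on Pelvic Fin Skeletal Muscle 1 and Adductor Skeletal Muscle 2. They are the only set C samples in tissues that also hold set A samples, so lost calls can reflect low precision. No gene had a set difference past the adjusted threshold. The count was 5 without Red Skeletal Muscle 2 and 15 without Red Skeletal Muscle 1 or Pelvic Fin Skeletal Muscle 4.

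Extraocular muscle, which moves the eye, was set against the same 5 muscles. The gdf11b2 ligand was higher, 116 ± 48.2 (SD, n = 3) against 24.4 ± 8.48 (SD, n = 5 tissue means), a 5.23-fold difference with no overlap between samples (log2 2.39 ± 0.52 (SE), adjusted p = 0.000611; 3.46 with pathway scaling). The activin beta A gene inhbab1 was also higher (54.6 ± 73.3 against 14.5; 2.13). Lower were smad4aa1 (65.1 ± 44.2 against 439 ± 250; −2.44 ± 0.47 (SE), adjusted p = 0.000179), inhbcb2 (−2.32), bambia1 (−1.95), inhbbb2 (−1.70), smad4aa2 (−0.89), acvr1ab2 (−0.88) and smad2a2 (−0.64). The mstna1 difference did not pass (0.59), and Extraocular Muscle 2 held 3 mstna1 counts, a level of 2.10 against 1350 and 1780 in its replicates. By list, 3 of 15 ligands (2 higher, 1 lower), 3 of 10 receptor-regulated and common Smads, 1 of 10 type I receptors, 1 of 2 bambi probes and 1 of 2 inhbcb probes were called, with fsta added as lower when adjusted over the list alone. edgeR's quasi-likelihood test called 2 genes higher and 7 lower. Pathway scaling and TMM gave 6 higher and 5 lower, DESeq2 8 and 5, tbp 4 and 4, and the positive controls 28 and 0. With pathway scaling smad4aa2 (−0.16) and acvr1ab2 (−0.32) no longer passed, and smad2a2 turned to 0.14. The calls of inhbab1 (2.56), smad4aa1 (−1.97), inhbcb2 (−2.37), bambia1 (−1.17) and inhbbb2 (−1.34) stayed. The sets as a block left 9 calls, and within set A 2 were higher and 5 lower (13 genes at an unadjusted p below 0.05). The count was 4 without Extraocular Muscle 2 or Extraocular Muscle 3 and 21 without Extraocular Muscle 1, whose counts of inhab1, inhab2, mstnb1 and mstnb2 were 201, 173, 206 and 173. The calls of gdf11b2 and smad4aa1 held without any 1 sample. Without Extraocular Muscle 2, acvr1ab2 (−0.51), bambia1 (−1.68), inhbbb2 (−1.27), inhbcb2 (−1.75), smad2a2 (−0.39) and smad4aa2 (−0.59) no longer passed. Without Extraocular Muscle 3 the same held for acvr1ab2 (−0.94), bambia1 (−1.75), inhbbb2 (−1.48), inhbcb2 (−1.97), smad2a2 (−0.69) and inhbab1 (0.05), while smad4aa2 moved to −1.37. Without Extraocular Muscle 1, inhbcb2 was −4.40 and inhbbb2 −2.77. The inhbcb2 call was also lost without Caudal Skeletal Muscle 1 (−2.29), and that of smad2a2 without Caudal Skeletal Muscle 1 (−0.58), Epaxial Skeletal Muscle 3 (−0.61), Hypaxial Skeletal Muscle 1 (−0.61), Hypaxial Skeletal Muscle 2 (−0.63) or Adductor Skeletal Muscle 3 (−0.61).

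Ovaries and testes were compared as the gonads of each sex; sex and gonad type are 1 comparison here. Ovaries held more of the activin beta A gene inhbab1, 153 ± 133 against 4.77 ± 0.54 (SD, n = 3 each; log2 4.98 ± 1.03 (SE), adjusted p = 0.00027), although Ovaries 3 read only 2.42. Receptors of both types were higher in ovaries: acvr1aa1 (18.4 ± 12.2 against 2.38 ± 0.622; 2.89), acvr1aa2 (2.49), acvr1ba1 (1.88), acvr2ba1 (2.74), acvr2ba2 (2.56) and acvr2bb (1.58). The probes of acvr2ba1 and acvr2ba2 share a target, so these are not separate observations. The activin beta B gene inhbbb1 (2.54) and the common Smad smad4bb2 (1.43) were higher in ovaries too. The beta A gene inhbaa2 (10.1 ± 6.37 against 32.7 ± 11.7; −1.67) and the receptor acvr2ab2 (−1.48) were lower. Over all 49 genes, 14 had no overlap between the samples of each side, which chance gives for 10% of genes with 3 against 3. By list, 3 of 15 ligands (2 higher), 3 of 10 type I receptors (all higher), 4 of 7 type II receptors (3 higher; 5 adjusted over the list alone) and 1 of 10 Smads (0 over the list alone) were called. edgeR's quasi-likelihood test called 9 higher and 2 lower. Pathway scaling gave 7 and 3, ef1a with tbp 13 and 1, tbp 18 and 0, and the positive controls 13 and 0; with the negative controls subtracted 2 genes passed, both higher. Within set A, which holds both tissues, 8 were higher and 3 lower. The calls of inhbab1, acvr1aa1, acvr1aa2 (1.62 without Ovaries 3) and acvr2ba1 held without any 1 sample. Calls lost without Ovaries 3 were acvr2ba2 (1.76), acvr2bb (1.14), acvr1ba1 (1.41), inhbaa2 (−1.33) and acvr2ab2 (−1.45). Those lost without Ovaries 1 were inhbbb1 (1.78), smad4bb2 (1.44) and acvr2ab2 (−1.36), and without Ovaries 2 smad4bb2 (0.73) and inhbaa2 (−1.58). Leaving out Testes 1 ended acvr1ba1 (1.86), inhbbb1 (2.37), smad4bb2 (1.28), inhbaa2 (−1.44) and acvr2ab2 (−1.48). Leaving out Testes 2 ended acvr1ba1 (1.89), inhbbb1 (2.30), smad4bb2 (1.44) and acvr2ab2 (−1.53), and leaving out Testes 3 ended acvr1ba1 (1.88), smad4bb2 (1.59) and acvr2ab2 (−1.44). The count was 6 without Testes 1 and 7 without Testes 2.

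Heart was compared with the bulbus arteriosus, the elastic outflow vessel of the teleost heart. The common Smad smad4ab2 was 6.50-fold higher in Heart, 116 ± 22 against 17.8 ± 4.48 (SD, n = 3 each; log2 2.70 ± 0.61 (SE), adjusted p = 0.00252). Type I receptors were higher in Heart for 3 of 10: acvr1ca1 (62.4 ± 13.6 against 10.6 ± 4.50; 2.60), acvr1bb1 (158 ± 3.92 against 38.2 ± 7.09; 2.04) and acvr1ab2 (1.26). Of the 7 type II receptors acvr2ba2 (2.25) and acvr2ba1 (1.85), which share a probe target, were higher, and acvr2bb was lower (10.4 ± 5.52 against 42.7 ± 2.86; −1.89 ± 0.47 (SE), adjusted p = 0.00454). The Smad smad2a2 was higher (0.80) and smad4bb2 lower (−1.48). Adjusted over the list alone, 4 type II receptors, 4 Smads and fsta passed; no ligand did either way. Over all 49 genes, 22 had no overlap between the samples, against a chance share of 10% per gene. edgeR's quasi-likelihood test called 7 higher and 2 lower, while pathway scaling and TMM gave 8 and 11, ef1a with tbp 3 and 10, tbp 2 and 12, DESeq2 10 and 11, and the positive controls 1 and 0. Heart lies in set C and the vessel in set A, so no value within a set can be had. With the sets as a block 2 genes were called, both higher in Heart. That block's difference between sets C and A rests on Pelvic Fin Skeletal Muscle 1 and Adductor Skeletal Muscle 2, so lost calls can reflect low precision. The count was 3 without Bulbus Arteriosus 1, 4 without Bulbus Arteriosus 2 or Heart 2, 14 without Bulbus Arteriosus 3, and 1 without the 8 samples of few detected genes. Without any 1 sample smad4ab2, acvr1bb1 and acvr2bb kept their calls. Leaving out Bulbus Arteriosus 1 ended acvr1ab2 (1.24), acvr1ca1 (2.26), acvr2ba1 (1.42), acvr2ba2 (2.06), smad2a2 (0.68) and smad4bb2 (−0.94). Leaving out Bulbus Arteriosus 2 ended acvr1ca1 (2.63), acvr2ba1 (2.15), acvr2ba2 (1.85), smad2a2 (0.76) and smad4bb2 (−1.62). Leaving out Heart 2 ended acvr1ca1 (2.42), acvr2ba1 (1.87), acvr2ba2 (2.13), smad2a2 (0.74) and smad4bb2 (−1.66). For Heart 1 these were acvr2ba1 (1.85), acvr2ba2 (2.00) and smad2a2 (0.65), and for Heart 3 acvr1ca1 (2.59), acvr2ba1 (1.82) and smad4bb2 (−1.12).

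Brain was compared with Retina as a pair of neural tissues. Of the type I receptors, 7 of 10 were higher in Brain: acvr1ab2 was 5.81-fold higher (662 ± 69.5 against 114 ± 17, SD, n = 3 each; log2 2.54 ± 0.37 (SE), adjusted p = 3.47e-07), followed by acvr1ca1 (2.52), acvr1ab1 (2.48), acvr1bb1 (2.16), acvr1ba2 (2.04), acvr1bb2 (1.82) and acvr1aa1 (1.82). The growth factor gene gdf11b2 had the largest difference, 127 ± 94.5 against 16.7 ± 1.21 (2.92 ± 0.77 (SE), adjusted p = 0.00337). Of the 7 type II receptors 4 were higher, among them acvr2ba1 (2.33), acvr2ab2 (1.88) and acvr2ba2 (1.76), and the activin beta B gene inhbbb2 was higher (1.85). In addition 4 of the 10 receptor-regulated and common Smads were higher, and these numbers were the same adjusted over the list alone. In all, edgeR's quasi-likelihood test called 17 genes, all higher in Brain. Over all 49 genes, 28 had no overlap between samples (chance share 10% per gene). With pathway scaling 9 were higher and 7 lower. By list, 6 of the 10 type I receptors were still higher and 0 lower. The type II receptors had 1 higher and 1 lower, and the ligands 2 and 1. None of the receptor-regulated and common Smads stayed higher, and smad4bb2 was lower (−1.74). Both bambi probes, fsta and 1 inhbcb probe were lower as well. TMM gave 4 and 8, DESeq2 7 and 8, tbp 3 and 2, and the positive controls 1 and 0. Brain lies in set A and Retina in set B, so the tissue and the set cannot be told apart. Calls ended without Retina 1 for acvr1bb2 (1.73) and acvr1ca1 (2.18), without Retina 2 for acvr1bb2 (1.80), acvr2ba2 (1.76) and inhbbb2 (1.82), without Retina 3 for acvr1aa1 (1.55) and acvr2ba2 (1.57), and without Brain 1 for acvr2ba2 (1.64).

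The panel held 21 pairs of gene duplicates, and the share of each pair's counts on each copy changed between tissues in 17. The largest changes were in smad4aa, acvr1ba and acvr1ca (F = 11.1, 10.7 and 10.7; adjusted p = 5.22e-12 each, edgeR's quasi-likelihood test of copy by tissue). For smad4aa1 the median share over tissues was 15.5% and the lowest 9.28% ± 3.64 (SD, n = 3) in Heart; probes may differ in efficiency, so only the change of a share between tissues can be read. The muscles were divided: the share was 59.1% ± 2.71 (SD, n = 2) in Caudal, 54.6% in Epaxial, 51.6% in Hypaxial and 46.2% in Pelvic Fin Skeletal Muscle, against 25.7% in Extraocular Muscle, 19.8% in Adductor and 12.9% in Red Skeletal Muscle. The acvr1ba1 copy took 90.7% ± 4.73 (SD, n = 3) in Distal Intestine and 24.4% ± 8.63 (SD, n = 4) in Adductor Skeletal Muscle. The gdf11b1 copy took 93.1% ± 2.45 (SD, n = 3) in Cardiac Stomach and 25.7% ± 25.7 (SD, n = 3) in Head Kidney. For the beta B pair, inhbbb1 took 68.9% ± 8.65 in Ovaries and 5.94% ± 4.67 in Caudal Skeletal Muscle. No change was detected for inhab (adjusted p = 0.827), mstnb (0.202), acvr2ba (0.193) and acvr1bb (0.0838; below 0.05 without Ovaries 1, Ovaries 2, Tongue 2 or Tongue 3, with 0.0453, 0.0383, 0.0344 and 0.0284); inhab and acvr2ba have probes that share a target, so their copies are not read separately. With the negative controls subtracted 11 pairs passed, and with the sets as a block 16.

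Correlation of the copies over the 23 tissue means was computed as well, with 100000 permutations and adjustment over the 21 pairs. The median r of the pairs was 0.826 against 0.461 for the 1155 pairings of genes that are not duplicates, and 19 pairs had an adjusted p below 0.05. Centring each tissue on its pathway mean gave medians of 0.589 and −0.0453, and 14 pairs. The lowest r belonged to acvr1ba, at 0.276 (permutation p = 0.204, adjusted p = 0.204) with rho 0.424 (permutation p = 0.045, adjusted p = 0.0472), 0.415 without the 2 farthest tissues and 0.506 over the 13 tissues wholly in set A. Next was inhbab, with r 0.336 (permutation p = 0.115, adjusted p = 0.121), rho 0.634 (permutation p = 0.00156, adjusted p = 0.00193), 0.655 without the 2 farthest and 0.0501 in set A. For inhbaa r was 0.462 (permutation p = 0.0256, adjusted p = 0.0283), rho 0.447 (permutation p = 0.0336, adjusted p = 0.0372), 0.331 without the 2 farthest and 0.113 in set A. For inhbbb r was 0.483 (permutation p = 0.0196, adjusted p = 0.0228), rho 0.657 (permutation p = 0.00094, adjusted p = 0.00123), 0.349 without the 2 farthest and 0.663 in set A. For gdf11b r was 0.485 (permutation p = 0.0192, adjusted p = 0.0228), rho 0.403 (permutation p = 0.0578, adjusted p = 0.0578), 0.507 without the 2 farthest and 0.812 in set A. The highest r were inhab 0.988, acvr1ab 0.980 and acvr1bb 0.958, with rho 0.947, 0.983 and 0.951. Their permutation p was 1e-05, the smallest that the permutations can give (adjusted p = 2.1e-05 for r and 2.33e-05 for rho). Without the 2 farthest tissues their r was 0.936, 0.974 and 0.943, and in set A it was 0.989, 0.967 and 0.933. Sets B and C hold 4 whole tissues each, too few for a value. The inhab and acvr2ba pairs have probes that share a target, so part of their r is built in, and both count in the median of 0.826.

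**Figure D4:**
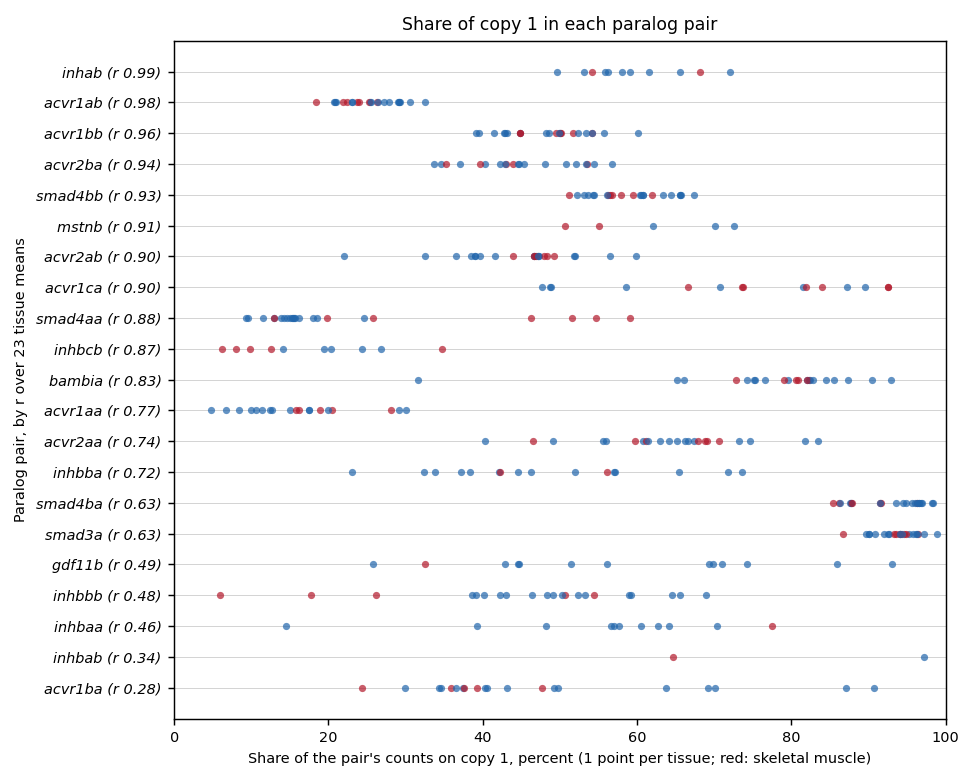
Share of each pair's counts on copy 1 (horizontal, percent), 1 point per tissue with enough counts (red, skeletal muscle; blue, other tissues), for the 21 pairs ordered by r over the 23 tissue means (vertical). The shares of smad4aa in muscle run from 12.9% to 59.1%, and those of acvr1ba from 24.4% to 90.7%.

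In single samples of unrelated tissues the counts of inhab1, inhab2, mstnb1 and mstnb2, the inhibin alpha and second myostatin genes, moved together. These genes were singled out after their values were seen. Other genes of the panel also rose with inhab2, as given further below, so the movement is not particular to these 4. Over the 64 samples outside the gonads, each taken relative to its tissue, mstnb1 followed inhab2 with r 0.776 (permutation p = 1e-05, the smallest possible, adjusted p = 1.67e-05 over 5 relations) and rho 0.787 (permutation p = 1e-05, adjusted p = 1.67e-05). For mstnb2 r was 0.743 and rho 0.733, with the same p-values. For inhab1 r was 0.868 and rho 0.859, a relation built in by its probe, which also binds inhab2. Without the 2 farthest samples, Pelvic Fin Skeletal Muscle 3 and Extraocular Muscle 1, r was 0.741 for mstnb1, 0.701 for mstnb2 and 0.851 for inhab1. Within sets A, B and C (38, 12 and 13 samples) the mstnb1 relation was 0.854, 0.873 and 0.420, mstnb2 was 0.826, 0.673 and 0.404, and inhab1 was 0.889, 0.593 and 0.940. Over all 64 samples no relation of the negative controls to inhab2 passed the threshold, with r 0.106 (permutation p = 0.479) and rho 0.173 (permutation p = 0.261), 0.0931 without the 2 farthest, and 0.437, 0.274 and −0.369 in the sets. The ratio of tbp to actb did, with r 0.460 (permutation p = 0.00171, adjusted p = 0.00214) and rho 0.480 (permutation p = 0.0015, adjusted p = 0.00187), 0.409 without the 2 farthest, and 0.687, 0.607 and 0.138 in the sets. The counts of the 4 genes in that order were 242, 122, 175 and 69 in Spleen 1, 182, 85, 121 and 46 in Head Kidney 1, and 186, 63, 59 and 71 in Pelvic Fin Skeletal Muscle 4.

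**Figure D5:**
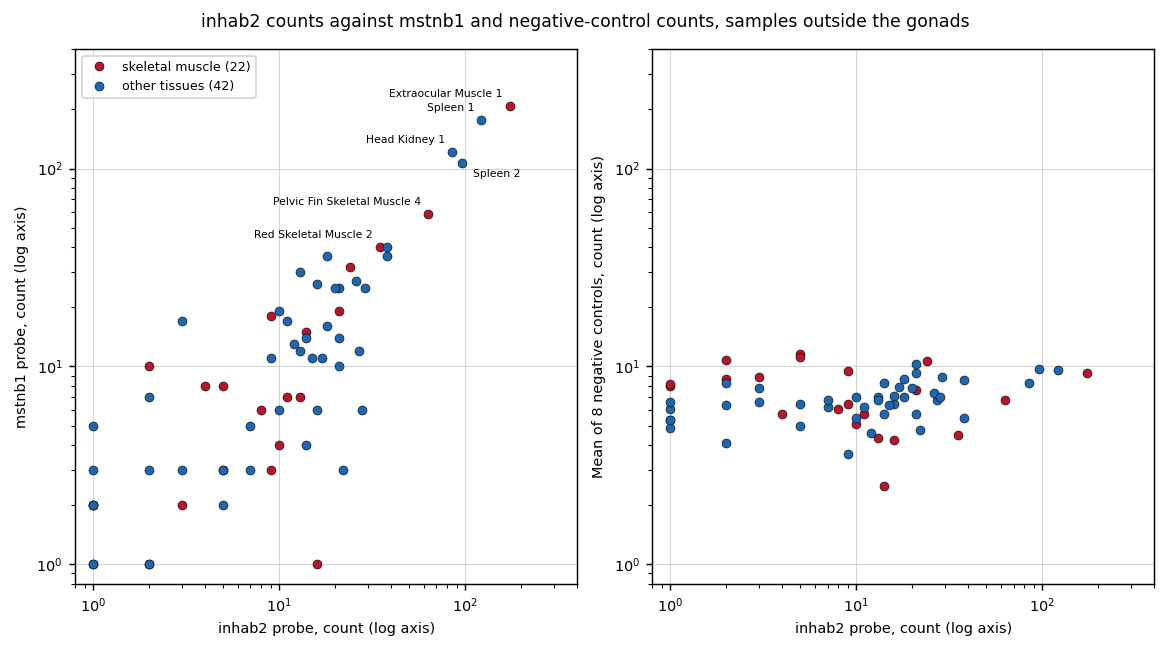
Counts of mstnb1 (left, vertical, log axis) and the mean count of the 8 negative controls (right, vertical, log axis) against counts of inhab2 (horizontal, log axis), 1 point per sample for 22 skeletal muscle samples (red) and 42 others outside the gonads (blue). Extraocular Muscle 1 has 173 inhab2 and 206 mstnb1 counts, while no sample's negative controls average above 11.5.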

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

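The tests of what lies behind each of the 3 patterns were chosen only after the result was seen; the search for samples far from their replicates and the regroupings of samples were planned.

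In the tissues with 4 replicates, a sample counted as far from the rest when its gap to the nearest replicate, as a share of the group's range, exceeded Dixon's 95% critical value. Of 104 such tests 10 passed, where chance gives 5.2. In Pelvic Fin Skeletal Muscle 4 the gap share was 0.846 for acvr1bb1 (293 against 98.3 to 128), 0.843 for acvr2ba2 (195 against 50.6 to 73.3), 0.877 for gdf11b2 (77.7 against 4.82 to 13.8), 0.926 for inhab1 (466 against 2.23 to 36.7), 0.882 for mstnb2 (178 against 2.23 to 22.9), 0.958 for smad4bb1 (220 against 135 to 138) and 0.866 for smad6a1 (276 against 32.1 to 64.8), all as reference-scaled counts. In Pelvic Fin Skeletal Muscle 2 it was 0.862 for smad4aa1 (669 against 140 to 213). In Adductor Skeletal Muscle 1, which holds 511 pathway counts, it was 0.853 for acvr1ca1 (199 against 354 to 381) and 0.923 for inhbbb2 (69.6 against 38.1 to 40.5).

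The first pattern lies in the authors' table, where Caudal Skeletal Muscle, Red Skeletal Muscle, Heart and Gill read low against the counts. Caudal Skeletal Muscle ranks 3, 3, 3, 4 and 4 for mstna1, fsta, smad4aa1, inhbcb2 and mstnb1, and 1 for each on 1 scale. Its rank moves from 4 to 1 for inhbab2, 11 to 5 for mstnb2, 8 to 6 for acvr1ca1 and 6 to 2 for acvr1ca2. Lower expression relative to the reference genes is argued against for Caudal Skeletal Muscle, Red Skeletal Muscle and Heart. Their median gene on 1 scale lies at least 0.27 log2 above the mean of the 13 tissues wholly in set A, and above 0 in every sample. That scale still divides by the reference genes, which are low in muscle, so it cannot tell whether expression as such is lower. For Gill the values argue against either a lower scale or lower expression relative to the reference genes as the whole cause. Its scale lies 1.29 log2 below set A. The median moved from −2.04 in the table to −0.77 on 1 scale, and every sample stayed below 0 there (−1.14 to −0.47). Normalization in separate sets stays open as a candidate explanation: the reference genes and positive controls of each set predict a gap of 1.294 log2 (2.45-fold), the gap found. That prediction rests on 2 samples of mixed tissues placed in set C as the best match of 12 placements; over all 12 the gap predicted runs from 1.19 to 1.32. The scale of set B, which needed no such placement, was predicted at log2 12.16042 and found at 12.16040.

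The second pattern is that most genes lie higher in skeletal muscle relative to the reference genes. Counts near background are argued against as the whole cause, since 19 of the 28 calls stayed after the negative controls were subtracted, and so are separate sets, since 18 genes were higher within set A alone. For mstna1, low reference genes in muscle are excluded as the whole cause: its lowest difference over 6 other scalings was 2.65 (adjusted p = 0.0017 there; highest over those scalings). For the panel as a whole, a general excess in muscle and low reference genes cannot be told apart: the median is 0.65 with tbp and −0.87 with the positive controls, and its −0.31 with pathway scaling decides nothing, since that scaling centres the panel. A biological difference between muscle and other tissues stays open, as does the extraction method, which varied by tissue and was not tested.

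The third pattern is the joint movement of inhab1, inhab2, mstnb1 and mstnb2 in single samples of unrelated tissues; the inhab1 probe also binds inhab2, so that part is built in. RNA from the gonads is argued against, since mstnb1 holds 0.00492 counts per inhab2 count there and gained 1.11 per inhab2 count within the 14 other tissues (SE 0.156) and 1.19 within the muscles (SE 0.166). Assay background is argued against as the whole cause, since the negative controls gained 0.0267 per inhab2 count (SE 0.0108), a small slope but not 0. Genomic DNA carried over with the RNA stays open as a hypothesis, since it could give unrelated single genes about 1 count for each other. Against this, mstnb2 gained 0.42 (SE 0.0488), acvr2ba1 0.21 and inhbab1 0.18 in the other tissues, although mstnb2 gained 1.05 in the muscles (SE 0.0337). Which probes span exon boundaries was not analysed here. The groups give no biological explanation, so none was tested.

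Random regroupings of the samples gave at most 25 genes for variation among the 23 tissues against 49 found, 69 enriched pairs against 184 and 1 duplicate pair against 17. For the muscle class, where tissues were regrouped, the highest was 25 genes against 28 found, a small margin. In each of these 4 the real grouping alone of 100 reached its count, a share under 0.05. For variation among the 7 muscles the highest was 25 against 10 found, for red muscle 19 against 9 and for extraocular muscle 23 against 9, so chance cannot be excluded. The comparisons of 3 with 3 samples have 10 splits, too few for a share under 0.05; the real and highest other counts were 11 and 6 for Ovaries against Testes, 9 and 0 for Heart against Bulbus Arteriosus, and 17 and 0 for Brain against Retina.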

How the results depend on the processing

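The scalings other than pathway scaling, limma, background subtraction, DESeq2, the sets and the omitted sample groups were alternatives chosen after seeing the data; the others were planned. Of 2247 values of named genes under alternatives 1984 kept direction and side of the threshold, 231 lost the call, 11 gained it and 21 reversed; of 2913 without 1 sample, 2820 kept it, 86 lost it, 5 gained it and 2 reversed. Of 190 numbers of calls, 135 stayed within 1.5 times with the same leading direction, 30 moved and 25 reversed the leading direction. Unless said otherwise the cause was not tested. Depth limits genes under about 20 counts, where background is 2.5 to 11.5.

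Numbers of calls follow, higher and lower in parentheses. Muscle class (28): pathway scaling 12 (5/7), samples as units 48, TMM 6, tbp 15, positive controls 23 (2/21), DESeq2 16 (6/10); within set A 18 and set C 8, with fewer tissues. Red muscle (9): pseudocount 1 gave 4 (0/4), pseudocount 50 18 (10/8), pathway scaling 15 (8/7), only the tissues compared 1 (0/1), limma 10 (3/7), ef1a with tbp 2 (0/2), tbp 6 (0/6), positive controls 1 (0/1), DESeq2 13 (6/7), joint-count samples out 6 (0/6), set block 0 and within set C 0 (edgeR; 11 unadjusted each). The replicate block gave 15 (13/2). Samples of equal replicate number were hardly more alike than others (mean r 0.017 for equal numbers, −0.00787 for others). Such low values cannot tell whether equal numbers mark the same fish. Extraocular muscle (9): pseudocount 1 15 (1/14), pathway scaling 11 (6/5), only the tissues compared 3 (1/2), background subtracted 9 (5/4), TMM 11 (6/5), positive controls 28 (28/0), DESeq2 13 (8/5), joint-count samples out 22 (3/19), samples unlike their replicates out 4 (3/1). Ovaries against Testes (11): only the tissues compared 7, background subtracted 2, tbp 18. Heart against Bulbus Arteriosus (9): pseudocount 50 10 (4/6), pathway scaling 19 (8/11), background subtracted 4 (4/0), TMM 19 (8/11), ef1a with tbp 13 (3/10), tbp 14 (2/12), positive controls 1, DESeq2 21 (10/11), without 8 low samples 1, samples unlike their replicates out 15 (10/5), set block 2. Brain against Retina (17): TMM 12 (4/8), tbp 5 (3/2), positive controls 1, DESeq2 15 (7/8). The 7 muscles (10): pseudocount 50 20, only the tissues compared 2, within set A 3, within set C 2. Enriched pairs (184): pseudocount 50 84, log2 minimum of 2 71. Duplicates (17): background subtracted 11.

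Without 1 sample each, the 7 muscles gave 7 to 18, red muscle 5 to 15, extraocular muscle 4 to 21, Ovaries against Testes 6 to 10 and Heart against Bulbus Arteriosus 3 to 14.

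Reversed genes: acvr1ca1 in Tongue was −0.12 with pseudocount 1, −0.14 with 50, −0.21 with limma, −2.10 with unlike samples out and −2.07 without Tongue 3; acvr1ca2 in Tongue −1.86 and −1.84 in the last 2, where Tongue 3 is the cause. In the muscle class, pathway scaling gave acvr2ab2 −0.0194 and inhbbb2 −0.0348, and positive controls acvr2ab1 −0.43, acvr2ab2 −0.65, bambia1 −0.16, bambia2 −0.0883, inhbbb2 −0.62 and mstnb1 −0.00893. In extraocular muscle smad2a2 was 0.14 with pathway scaling, 0.0112 with TMM, 0.22 with DESeq2 and 1.07 with positive controls, which also gave acvr1ab2 0.93, bambia1 0.0425, inhbbb2 0.20 and smad4aa2 0.74.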

Other observations

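Apart from the numbers of enriched and depleted genes, the tests in this part were chosen only after the result was seen. The tissues with the most depleted genes were Pyloric Caeca with 28, Head Kidney with 26 and Distal Intestine with 25 of the 49, and with pathway scaling these were 6, 3 and 6. Their enriched genes ran the other way, with 4, 1 and 3 by the reference genes and 7, 4 and 8 with pathway scaling; in Head Kidney the 1 gene was gdf11b2. The most enriched genes were 24 in Pelvic Fin Skeletal Muscle and 20 each in Caudal Skeletal Muscle and Hypaxial Skeletal Muscle, and 6, 9 and 7 with pathway scaling. The 24 include inhab1, inhab2, mstnb1 and mstnb2, at mean counts of 51, 23.75, 21 and 20.5. Pelvic Fin Skeletal Muscle 4 read 466 for inhab1 and 178 for mstnb2 as reference-scaled counts, against at most 36.7 and 22.9 in its replicates. Without that sample 179 pairs were enriched over all tissues, against 184 with it.

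In 48 of 70 samples the pathway profile lay closest to other samples of its own tissue, and in 22 to another tissue; 15 of the 22 were muscles closest to another muscle. Extraocular Muscle 2 was closest to Visceral Fat (r 0.520 across genes, 0.224 with its own tissue), and Tongue 3 was also closest to Visceral Fat (0.687 against 0.090). The other muscle sample closest to a tissue outside muscle was Red Skeletal Muscle 2, to Spleen (0.327 against 0.174). Ovaries 3 was closest to Testes (0.495 against 0.459) and held 341 inhab1 counts, against 17796 and 14003 in its replicates. Head Kidney 1 was closest to Spleen (0.746 against 0.477), and Pelvic Fin Skeletal Muscle 4 to Red Skeletal Muscle (0.577 against 0.0126). Genes are not independent, so these r carry no p-value.

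In the authors' table, inhab1 equals the inhab1 probe minus the inhab2 probe, with 0 as the lowest value, in 20 of 23 tissues; 4 tissues are listed at 0, Epaxial Skeletal Muscle, Tongue, Gill and Visceral Fat. Variation between replicates of a tissue had a first axis with 29.1% of the variance and a second with 11.9%.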
